A study of Homo sapiens with 6 samples.

How the data were processed

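RNA sequencing of 6 samples of MDA-MB-231-P3 cells was used, 3 labelled as control siRNA and 3 as siRNA against Uc003xsl.1, delivered with a Lipofectamine reagent per the labels' protocols. Per the labels' protocols, strand-specific libraries were made from the mRNA fraction by dUTP marking of the second strand and sequenced as paired ends of 150 bases, reads were aligned to the human genome hg19 with HISAT2, and the deposited values are FPKM made by the authors from read counts per gene. The submitters' processing notes name Bowtie2 and RSEM without versions, so the sources differ on the aligner. The annotation, its release and the filter that left 13498 rows are not given in the sources used here. Per the labels' protocols the authors called genes at a false discovery rate under 0.05, and no such table was used here. Read counts were not used here, the FPKM values showed no steps of whole reads, and the depth of each sample is therefore unknown and no counting interval was given.

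One table holds all 6 samples, and the 6 files of single samples were identical to its columns. Each column was assigned to its sample by name. The sums of FPKM were 161743, 191907 and 147782 over the control columns and 163083, 148672 and 194608 over the Uc003xsl.1 siRNA columns. Some 20 symbols occur more than once (59 rows), 22 rows carry a calendar date in place of a gene name, as spreadsheet programs make of some symbols, and 398 rows carry assembled-transcript identifiers (MSTRG). Symbols were matched to GENCODE release 44 lifted to GRCh37, which is the same assembly as hg19, directly or through older symbols and RefSeq synonyms. A match was found for 12007 rows (89.0%), and loci and the exon number of the canonical transcript come from that annotation, which is not the one the authors used. Genes that overlap or have near-identical copies are uncertain wherever the quantification could split their reads.

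Before any comparison, the columns of a group were compared with each other. Multiples and constants read from a few rows were then checked on every row for each order of the 3 columns, with a tolerance of 1e-05 FPKM. All nonzero rows met the relation, with largest deviations of 1.2e-06 FPKM in the control group and 8.34e-06 FPKM in the Uc003xsl.1 siRNA group. In simulated independent libraries of 13338 genes 0 rows met it, and in simulated rescaled copies 13338 did. Whether the unscaled value is 1 library or a mean of several is not given in the sources used here. The mean of the 3 columns was used as the value of a group, counted as 1 sample. Because the added constants raise that mean by under 0.02 FPKM, folds are printed only where the lower group is at 1 FPKM or more, and FPKM values are printed otherwise.

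The moderated linear-model test, gene set tests, permutation tests and sample splits chosen before the data were examined need a spread between samples. That spread is fixed by the constants here, so these were left out and sizes of difference are described in their place. Differences are log2(FPKM + 1) in the Uc003xsl.1 siRNA group minus that in the control group, a scale that understates differences of low genes, and folds are ratios of FPKM. Genes with at least 1 FPKM in at least 3 of the 6 columns and above 0 in both groups were compared, 10752 in all, and differences of at least 2-fold on the log2(FPKM + 1) scale were counted. On simulated values of 10329 genes, 98.0% of genes set 4-fold apart and 0.0494% of unchanged genes passed that size. The simulated noise, 0.3 (SD, log2), was assumed, since it cannot be measured with 1 sample per group, so these shares check the calculation and are not error rates of the comparison.

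The 20 gene lists were written before the data were examined. They cover NF-κB-induced cytokines, NF-κB feedback targets, NF-κB components, invasion and mesenchymal genes, angiogenesis, interferon-stimulated genes, mitosis, DNA replication, p53 targets, the unfolded protein and ATF4 response, cholesterol and fatty acid synthesis, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, immediate early genes, histones, mitochondrially encoded transcripts, and luminal, leukocyte, and fibroblast and endothelial markers. A list with at least 3 members compared, which held for 18, was described by the percentile of its median log2 difference among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. This describes these values and is not a test across replicates. Listed genes without a row did not enter. Rows were found for 14 of 26 NF-κB-induced cytokines, 18 of 32 luminal and epithelial markers, 49 of 73 ribosomal protein genes and 33 of 40 interferon-stimulated genes. With the same assumed noise, lists of 20 genes set 2-fold apart were above the central 95% in 100% of cases and 7% of unchanged lists fell outside the central 95%. The unchanged lists were random draws of genes with independent noise. The 7% therefore checks the calculation and does not cover lists whose members vary together. Lists of YAP and TEAD targets and of MHC class I presentation genes were added after values had been seen.

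The rule for named genes fixed beforehand took CXCL8, NKRF, NFKB1, RELA and the target whatever their values, and further genes by adjusted p. With no p-values, the latter part was adapted after the column relation was known. It took the 10 genes with the largest lower and the 10 with the largest higher difference that have a symbol and at least 5 FPKM in the higher group, and from each list up to 4 members that differ by at least 2-fold, or otherwise the 2 with the largest difference. The same 10 and 10 among genes with 5 or more exons, the genes highest in one group and listed at 0 in the other, and other list members given with their values were chosen after values had been seen. Some genes that the rule takes are not reported here.

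In a search for words in 3′ UTRs, log2 differences limited to 2 in either direction were adjusted by linear regression for UTR length, GC content, exon number and transcript length. Each word of 6, 7 or 8 bases present in at least 50 of the genes was scored by the mean adjusted difference of genes with the word minus that of genes without it, divided by its standard error over genes (the standardised shift). UTRs of at least 30 bases came from the canonical transcripts. The search was repeated with words chosen on a random set of genes and measured on the genes left out of it, in both directions, a step added after the data had been seen. The search ranked the planted word first in 20 of 20 simulated cases over 4000 genes. Alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a mean of at least 5 FPKM, median-ratio scaling, quantile normalization and leaving out each column. Added after the data had been seen were the unscaled values, counting genes at 0 in one group, and genes with 5 or more exons only. A further one, also added then, kept genes with a 3′ UTR searched and no long match to the word CTCACA. Calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.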

Results

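Gene expression was measured by paired-end, strand-specific RNA sequencing of the mRNA fraction of MDA-MB-231-P3 cells. The labels describe these cells as a highly metastatic subline of triple-negative breast cancer, and MDA-MB-231 is an established human breast cancer line with mesenchymal features. Cells received small interfering RNA (siRNA) duplexes, which direct the cleavage of a matching transcript, either against the long noncoding RNA Uc003xsl.1 or as a control. The labels give 3 samples per group. The table holds 13498 rows with 1 FPKM value (sequenced fragments scaled to transcript length and to the mapped fragments of the sample) per gene and sample, and the depth of each sample is unknown because no read counts were used here.

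The 3 columns of each group did not vary independently. In the control group, each of the 13338 rows above 0 held a value b, the value 1.2b + 0.02 and the value 0.88b + 0.03, in FPKM, to within 1e-05 FPKM. In the Uc003xsl.1 siRNA group, each of the 13336 rows above 0 held b, 1.2b + 0.03 and 0.9b + 0.02 to within the same tolerance. The unscaled value b stood in column 1 in 12035 control rows, in column 2 in 237 and in column 3 in 1066. In the Uc003xsl.1 siRNA group these numbers were 13297, 19 and 20. The coefficient of variation between columns was accordingly nearly the same for every gene, with a 5th to 95th percentile range of 15.4% to 15.7% in the control group and 14.8% to 15.2% in the Uc003xsl.1 siRNA group, among genes with a mean of at least 1 FPKM. The columns of a group therefore carry 1 set of measurements, and each group was counted as 1 sample (n = 1 per group). A difference between the groups has no replicate check here, so no SD, p-value or test is given, and every difference below is between these 2 sets of values. Counts of genes at least 2-fold apart use the log2(FPKM + 1) scale, which understates differences of low genes. Some genes outside these counts are therefore over 2-fold apart by FPKM ratio.

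The comparison asked how the transcriptome differs after siRNA against Uc003xsl.1, with the series title naming the NF-κB/IL8 axis and the NF-κB repressing factor NKRF. The targeted transcript itself was not analysed here, because no row carries its identifier, so the group labels could not be checked against the target. CXCL8, which encodes the neutrophil-attracting chemokine interleukin 8 (chromosome 4, 74606236 to 74609433, hg19), was at 11.2 FPKM in the control group and 2.70 FPKM in the Uc003xsl.1 siRNA group, 4.16-fold lower (log2 difference -1.73). NKRF, a repressor of NF-κB-driven promoters (chromosome X, 118722300 to 118740406), was at 1.02 FPKM in the control group and 0.335 FPKM in the Uc003xsl.1 siRNA group. It did not pass the filter on low values and is in no count of genes compared. The NF-κB subunit genes NFKB1, at 7.97 and 6.58 FPKM, and RELA, at 15.4 and 16.5 FPKM, differed less, by log2 -0.24 and 0.10.

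Besides CXCL8, 2 further cytokine genes of the 9 compared among NF-κB-induced cytokines and chemokines were at least 2-fold lower in the Uc003xsl.1 siRNA group. CSF2, which encodes the myeloid growth factor GM-CSF, was at 5.65 FPKM in the control group and 0.195 FPKM in the Uc003xsl.1 siRNA group, and IL1B, encoding interleukin 1 beta, was at 1.67 and 0.0734 FPKM. None of the 9 was at least 2-fold higher on the log2(FPKM + 1) scale. The chemokine gene CCL5 went against the lower members, at 0.408 and 1.76 FPKM (log2 difference 0.97), short of 2-fold on that scale only because of the pseudocount. LIF, CSF1, VEGFA and IL11 lay within 2-fold. The list median (-0.17) was at percentile 9.51 of random lists matched on level, within their central 95%. NF-κB feedback, survival and adhesion targets were lower as a list, with a median of -0.29 over 22 genes at percentile 0.05, and 18 of the 22 were below the control value. PLAU, the urokinase plasminogen activator, was 2.31-fold lower (76.6 against 33.2 FPKM), PTX3 3.02-fold lower and IER3 2.04-fold lower, while NFKBIA, the inhibitor induced by NF-κB itself, was at 26.1 and 16.5 FPKM. ICAM1, at 2.19 and 4.41 FPKM, and SOD2, at 1.85 and 4.49 FPKM, were on the higher side but under 2-fold on the log2(FPKM + 1) scale. This list was back within the central 95%, at percentile 3.63, when a mean of at least 5 FPKM was required. Among 28 pathway components the median was -0.03 (percentile 17.3), and MYD88, the adaptor of Toll-like and interleukin 1 receptors, was the 1 gene at least 2-fold lower, at 4.62 and 1.00 FPKM.

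Invasion and mesenchymal genes were lower as a list in the Uc003xsl.1 siRNA group, with members on both sides. Of 23 compared, 9 were at least 2-fold lower and 4 at least 2-fold higher, with a median of -0.48, below all 10000 random lists. The lower members included the matricellular gene SPARC, 5.04-fold lower (31.8 against 6.31 FPKM), the intermediate filament gene VIM at 284 and 114 FPKM, the epithelial-mesenchymal transcription factor gene SNAI2 at 6.12 and 1.31 FPKM, and TGFBI, COL4A2, TNC, S100A4 and ITGB1. The higher members were the matricellular genes CTGF (11.9-fold, 38.7 against 460 FPKM) and CYR61 (4.03-fold, 286 against 1152 FPKM), the growth factor gene TGFB1 at 16.3 and 56.2 FPKM, and the matrix metalloproteinase gene MMP3 at 0.135 and 3.46 FPKM. Luminal and epithelial markers, included to detect another breast cell line, went the other way. All 15 compared, of 32 listed, were above the control value, 7 of them at least 2-fold, with a median of 0.55 at percentile 99.95. The simple-epithelium keratin genes KRT8 and KRT18 were at 100 and 102 FPKM in the control group and at 256 and 233 FPKM in the Uc003xsl.1 siRNA group. The tight junction gene CLDN4 was at 0.30 and 11.3 FPKM, the luminal transcription factor gene FOXA1 at 0.192 and 2.20 FPKM and KRT17 at 0.394 and 2.31 FPKM, while CLDN3 was listed at 0 in the control group and at 8.46 FPKM in the other. CLDN4 and CLDN3 have 1 exon and FOXA1 has 2, classes in which large differences were frequent. Values of 0 in one group alone were frequent among genes with 1 exon. KRT8, KRT18 and KRT17 have 7 or 8 exons. Markers of other cell types gave little to compare. The leukocyte marker LAPTM5, the 1 compared of its list, was at 83.6 and 36.2 FPKM, and the 3 fibroblast and endothelial markers compared had a median of -0.03 (percentile 37.3), with COL6A3 at 2.25 and 0.735 FPKM and ESAM at 6.41 and 7.09 FPKM. Angiogenesis factors were split, with 4 of 15 at least 2-fold higher, among them ADM (3.78-fold), EDN1 (4.05-fold) and EFNA1 (2.57-fold) together with VASH1, and TIMP3 at least 2-fold lower. Their median of 0.05 was at percentile 50.7, and at percentile 99.3 with a mean of at least 5 FPKM required. The list was not divided into genes that promote and genes that inhibit angiogenesis, so its median gives no direction of angiogenesis.

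Interferon-stimulated genes showed the most displaced median of the lists compared. Of 30 genes, 24 were at least 2-fold higher in the Uc003xsl.1 siRNA group and none was at least 2-fold lower, and the median of 1.54 lay above all 10000 random lists. The ubiquitin-like modifier gene ISG15 was at 23.0 FPKM in the control group and 1084 FPKM in the Uc003xsl.1 siRNA group (47.1-fold). IFI6 was 12.7-fold higher, the antiviral GTPase gene MX1 16.6-fold and IFI27 17.0-fold. The interferon regulatory factor gene IRF7 was at 4.83 and 33.9 FPKM. Genes of the unfolded protein and ATF4 response were also higher as a list, with a median of 0.53 over 33 genes above all random lists, 5 of them at least 2-fold higher and none at least 2-fold lower. ATF3 was 3.30-fold higher, PPP1R15A, which directs dephosphorylation of the initiation factor eIF2α, 2.40-fold, DNAJC3 2.94-fold and SDF2L1 2.08-fold. The chaperone gene HSPA5, a standard marker of the unfolded protein response, was on the other side, at 99.3 and 51.8 FPKM, and SLC7A11 at 7.99 and 3.77 FPKM. SLC7A11 was 2.12-fold lower by FPKM ratio and under 2-fold on the log2(FPKM + 1) scale.

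**Figure D1:**
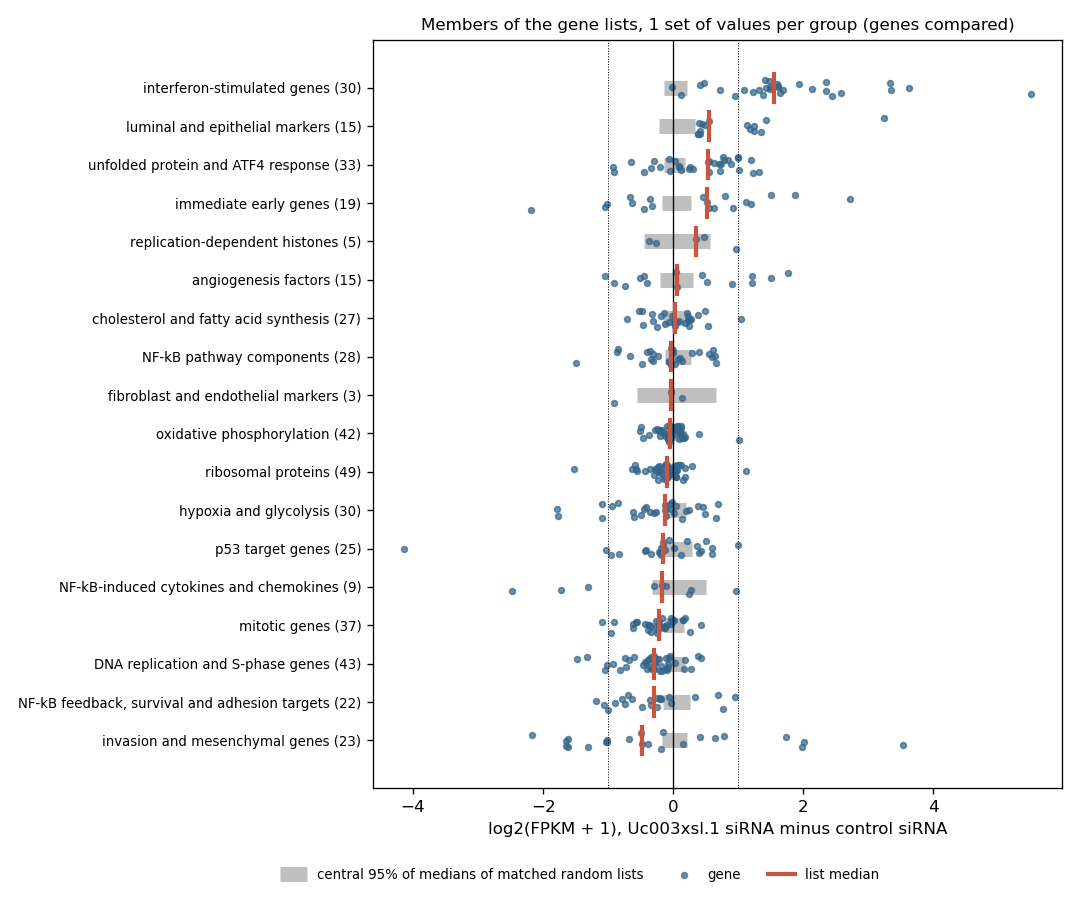
Each point is a gene and the horizontal axis is its log2(FPKM + 1) in the Uc003xsl.1 siRNA group minus that in the control group, by gene list with the number of genes compared, 1 set of values per group. Red marks are list medians, from -0.48 for invasion and mesenchymal genes to 1.54 for interferon-stimulated genes, grey bars hold the central 95% of medians of random lists matched on level, and dotted lines mark 2-fold.

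Cell cycle genes were lower by small amounts. The median of 43 DNA replication and S-phase genes was -0.29, below all 10000 random lists, and 37 of them were below the control value, 4 at least 2-fold. RRM2, a subunit of ribonucleotide reductase, was 3.19-fold lower, the thymidylate synthase gene TYMS 2.59-fold (42.7 against 16.5 FPKM), GINS2 2.36-fold and CDC6 2.13-fold. Mitotic genes had a median of -0.22 over 37 genes (percentile 0.11). KIF11, a spindle motor gene, was the 1 member at least 2-fold lower on the log2(FPKM + 1) scale, at 23.8 and 10.6 FPKM. By FPKM ratio, ASPM (2.09-fold lower) and CKAP2L (2.03-fold lower) also reached 2-fold. CCND1, the gene of the G1 cyclin D1, was 7.44-fold lower (155 against 20.8 FPKM). Among 25 p53 target genes, 2 were at least 2-fold lower (TRIAP1 and DDB2) and 1 higher (SESN2, 2.29-fold), with CDKN1A at 25.9 and 12.9 FPKM. The p53 list median of -0.15 was at percentile 2.08, and it was back within the central 95% with either other pseudocount, with a mean of at least 5 FPKM, with quantile normalization and with several other settings (percentiles 2.65 to 6.69). The 5 replication-dependent histone genes compared had a median of 0.35 (percentile 88.6), with HIST1H2AC at 5.84 and 12.4 FPKM and HIST1H3H at 0.547 and 1.15 FPKM.

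Metabolic and translation genes had medians within the central 95% of random lists, which for hypoxia and glycolysis depended on the setting. Hypoxia and glycolysis genes had a median of -0.12 over 30 genes (percentile 4.47), which lay below percentile 2.5 with either other pseudocount (1.16 and 2.38), quantile normalization (0.75) or a mean of at least 5 FPKM (0.45), among other settings. Lower members were the mitophagy receptor gene BNIP3L (3.91-fold), the glycolytic gene PGAM1 (3.45-fold, 203 against 58.9 FPKM), and the carbonic anhydrase genes CA12, at 1.97 and 0.387 FPKM, and CA9, at 1.35 and 0.101 FPKM. Cholesterol and fatty acid synthesis genes had a median of 0.04 over 27 genes (percentile 50.7), with IDI1 2.21-fold higher. Oxidative phosphorylation genes had a median of -0.04 over 42 genes (percentile 25.3). Ribosomal protein genes had a median of -0.09 over 49 genes (percentile 14.3), with RPL6 2.91-fold lower and RPS15 2.21-fold higher. No mitochondrially encoded transcript of the list had a row. Immediate early genes went both ways. Of 19 compared, 5 were at least 2-fold higher, among them PHLDA1 (9.85-fold), DUSP6 (2.94-fold) and NR4A1 at 0.922 and 6.01 FPKM, and 3 at least 2-fold lower, among them EGR1 (5.93-fold, 15.6 against 2.63 FPKM). Their median of 0.51 was at percentile 99.99, but at percentile 0.26 with a mean of at least 5 FPKM required, so the position of this list turns with the filter.

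Over all 10752 genes compared, 520 (4.84%) were at least 2-fold higher and 382 (3.55%) at least 2-fold lower in the Uc003xsl.1 siRNA group. The median log2 difference was 0.05, with a 5th percentile of -0.85 and a 95th percentile of 0.99, and the Pearson correlation of log2 values across genes, which are not independent replicates, was 0.919. The 10 genes with the largest differences toward lower values were CKAP4 (50.9 against 0.276 FPKM, chromosome 12, 106631659 to 106698057), TRIAP1 (21.9 against 0.303), GPX1 (157 against 9.39), YWHAG (76.5 against 4.99), MRPL50 (10.3 against 0.0639), POMGNT2 (10.7 against 0.134), ADAM19 (11.8 against 0.731), BASP1 (6.28 against 0.0167), CCND1 and HIST2H2AA4 (6.35 against 0.0356). GPX1 encodes a glutathione peroxidase. The low value of BASP1 comes almost wholly from the constants of the column relation, and HIST2H2AA4 has a near-identical copy, so its reads are uncertain. The 10 with the largest differences toward higher values included PTRF, the caveolar coat gene now named CAVIN1 (0.0929 against 192 FPKM, chromosome 17, 40554467 to 40575274), ISG15, TMEM115 (0.111 against 25.5), IFI6, CTGF, ZNF787 (2.45 against 35.8), SOCS5 (0.0244 against 9.88), MX1 and RABIF (0.0636 against 9.81).

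Genes with few exons were over-represented among these extremes. Canonical transcripts of 1 or 2 exons belonged to 8 of the 10 largest lower genes and 6 of the 10 largest higher genes, against 6.43% of all compared genes with an exon number. Among coding genes compared, 27.9% of those with 2 exons differed by at least 2-fold, and 16.4% of those with 1 exon. The share was 13.3% with 3 to 4 exons, 9.63% with 5 to 9 and 3.21% with 20 or more. List members named above with 2 exons include ISG15, TRIAP1, IER3, PHLDA1 and EGR1. CXCL8 and CSF2 have 4 exons, so comparisons limited to genes with 5 or more exons leave them out. The random lists were matched on level and not on exon number. Among genes with 5 or more exons, the largest lower differences were those of ADAM19, a metalloprotease gene of 23 exons, CCND1, the tetraspanin gene CD82 (7.52-fold), IMPAD1 (8.62-fold), PTBP3 (7.64-fold), SLC20A1 (5.25-fold), PCYOX1 (6.66-fold), CLIC4 (5.48-fold), GPAT3 (6.80-fold) and SLC25A32 (5.63-fold). The largest higher differences among them were those of IFI6, CTGF, MX1, IFI27, SPNS2 (0.344 against 7.27 FPKM), IRF7, FHL1 (0.167 against 5.91 FPKM), FST, the activin antagonist follistatin (8.55-fold), RAB10 (6.32-fold) and UHMK1 (6.49-fold).

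A further 149 rows were listed at 0 in the Uc003xsl.1 siRNA group alone and 147 in the control group alone. Those at 0 in the Uc003xsl.1 siRNA group included the noncoding RNA NORAD (58.3 FPKM in the control group), IRF2BP1 (54.0), RNF26 (34.1) and the AP-1 subunit gene JUND (29.5). Those at 0 in the control group included CCDC85B (53.2 FPKM in the Uc003xsl.1 siRNA group), ATXN7L3B (20.9), TSPYL1 (20.2) and CHMP1B (19.2). All of these have 1 exon. Of 155 coding genes with 1 exon, 56 (36.1%) were at 0 in one group alone, 34 in the Uc003xsl.1 siRNA group and 22 in the control group. Of 10853 coding genes with 2 or more exons, 24 were (0.221%). Genes with 2 exons held 12 of these 24, which is 2.51% of the 478 in that class. An exact 0 in such values can be a failed estimate, so these genes are given as listed at 0 and did not enter the counts of differences above.

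**Figure D2:**
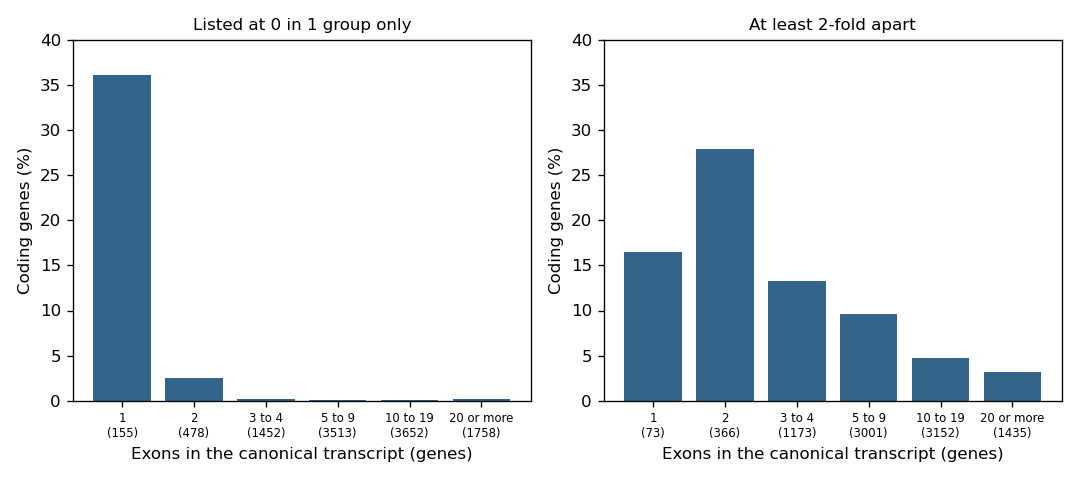
Bars give the percentage of coding genes, by the number of exons in the canonical transcript with the number of genes in parentheses, that were listed at 0 in one group alone (left) or differed by at least 2-fold between the groups on log2(FPKM + 1) (right). Genes with 1 exon stand out on the left at 36.1%, and genes with 2 exons on the right at 27.9%.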

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

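No paired analysis was possible because the columns of each group are rescaled copies of 1 set of values, so a replicate number marks no separate sample. For the same reason the planned fits without a variance trend, with sample weights, with the replicate number as a block, with a minimum fold in the test, with an estimated gene correlation, the rotation gene set test and the 10 splits of the samples were not run, and neither were the alternatives planned for read counts. The files of single samples hold the same values and give nothing to compare. The alternatives restricted to genes with 5 or more exons, to unscaled values, to genes without a 7- or 8-base CTCACA match, and with genes at 0 included were chosen after the data had been seen.

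The 520 genes at least 2-fold higher and 382 lower became 891 and 635 with a pseudocount of 0.1, because a smaller pseudocount shrinks low genes less, and 288 and 232 with a mean of at least 5 FPKM and 263 and 228 with genes of 5 or more exons only, where fewer genes were compared (5893 and 7723). Among genes with a 3′ UTR searched and no 7- or 8-base CTCACA match the lower count was 193, of 7635 genes compared, with 386 higher. This setting also left out genes whose 3′ UTR was not searched, so the fall from 382 is not due to matched genes alone. Of the lower genes, 329 had a 3′ UTR searched and 136 of these held a match. Counting genes at 0 in one group too gave 614 and 468. The difference of NKRF, a gene below the filter on low values, -0.60, was -1.37 with a pseudocount of 0.1, past 2-fold. Immediate early genes went from percentile 99.99 to 0.26 with a mean of at least 5 FPKM. That filter left out FOS, NR4A1, NR4A2 and ZFP36, all on the higher side. No compared member lay between -0.32 (SRF) and 0.46 (FOS), so the median crossed this gap, and neither percentile describes the list as a whole. The share of higher genes among those at least 2-fold apart was 57.6%, 51.7% with median-ratio scaling and 49.6% with quantile normalization.

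The lists above (4) or below (5) the central 95% of random lists were as many in each fit that left out 1 column. Their members were not the same, since p53 targets left the lower lists (percentiles 2.72 and 2.84) and hypoxia and glycolysis entered (1.86 and 2.05) without control siRNA replicate 2 and without Uc003xsl.1 siRNA replicate 2. In these fits the higher genes numbered 448 to 590, the lower genes 325 to 471, and NKRF and CXCL8 lay at -0.65 to -0.54 and -1.82 to -1.61. Leaving out a column removes no independent sample. It rescales most genes of a group alike, and differently the 2591 control rows and 614 Uc003xsl.1 siRNA rows with another column order, with the median of all genes between -0.05 and 0.16, so these ranges say nothing about stability. Among list percentiles, p53 targets crossed the 2.5 bound in 6 alternatives beyond the left-out columns, hypoxia and glycolysis crossed it in the other direction in 5, angiogenesis rose to 99.3 with a mean of at least 5 FPKM and to 99.7 without matched genes, and NF-κB feedback targets were back within the central 95% at 3.63 with a mean of at least 5 FPKM. Of single-gene differences and list percentiles over the alternatives other than left-out columns, 893 kept their side and size, 44 moved by over 1.5-fold, 12 went past their bound, 16 fell back within it and 1, that of immediate early genes, reversed. Over the left-out columns, 597 kept their side, 4 went past their bound and 23 fell back within it.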

Other observations

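The tests of genes at 0 in one group, of scaling and of few exons for interferon-stimulated genes, of longer matches (on genes not used to choose the words) and base composition for the hexamer, and of both added gene lists were chosen only after the results had been seen. YAP and TEAD target genes were higher in the Uc003xsl.1 siRNA group as a list, with a median log2 difference of 0.36 over 17 genes at percentile 99.2 of matched random lists. CTGF (11.9-fold) and CYR61 (4.03-fold), which are also members of the invasion list, ANKRD1 (3.02-fold, 79.8 against 241 FPKM), the tissue factor gene F3 (18.3 against 56.0 FPKM) and CRIM1 (33.8 against 92.3 FPKM) were at least 2-fold higher, while FOXF2 and NT5E were at least 2-fold lower. The YAP and TEAD list was written after values had been seen, so its percentile may partly restate them. No percentile without CTGF and CYR61 was calculated. MHC class I presentation genes had a median of 0.26 over 14 genes at percentile 98.2, with no member at least 2-fold apart, TAP1 at 8.06 and 12.7 FPKM and CALR at 95.6 and 163 FPKM. CXCL8 and CSF2 were thus lower in the same values in which interferon-stimulated genes were higher, and the chemokine gene CCL5, a target of both pathways, was at 0.408 and 1.76 FPKM.

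Coding genes listed at 0 in one group and above 0 in the other were concentrated among genes of 1 exon. The share was 36.1% with 1 exon against 0.221% with 2 or more. Genes with 2 exons lay between, at 2.51% (12 of 478), against 0.138% of those with 3 to 4. Loss or gain of expression after the knockdown would not be limited by exon number, and the 0.221% argues against it as the main origin. Low level with shallow sampling is argued against as well. Of the 1-exon coding genes at 5 FPKM or more in one group, 39.4% were at 0 in the other. Of 5830 such genes with more exons, 0 were at exactly 0. That count misses genes of 2 exons just above 0 in one group. Examples are BASP1 (6.28 FPKM in the control group against 0.0167), MRPL50 (10.3 against 0.0639) and SOCS5 (0.0244 against 9.88). A step in the quantification that dropped 1-exon genes, and some with 2 exons, separately in each group may account for the pattern. No step of this kind is given in the sources used here.

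Interferon-stimulated genes were higher by a median of 1.54. A scaling difference between the groups is argued against by the median of the list lying 1.49 above that of all genes. Distorted values in genes with few exons are argued against too, because 20 of the 25 members with 5 or more exons were at least 2-fold higher, with a median of 1.60 over the 25. A response to the transfected duplex and not to loss of the target cannot be told apart from an effect of the target, because only 1 group received a targeting siRNA, and a second duplex or a rescue would be needed. The biological explanation, loss of Uc003xsl.1, stays open in the same way and is untested.

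Genes whose 3′ UTR holds the hexamer CTCACA were lower on average in the Uc003xsl.1 siRNA group, most of all those with a longer match. The 8-base match was TCTCACAA and the 7-base match was TCTCACA or CTCACAA, words chosen on these same values. The median log2 difference was -0.19 in 255 genes with an 8-base match and -0.13 in 1276 with a 7-base match. It was 0.02 in 1613 with the hexamer alone and 0.10 in 6022 without it. The hexamer had the lowest standardised shift of 4096 hexamers (-11.7, mean shift -0.14, 3144 of 9166 genes), where 100 shuffles of the differences over genes gave extremes of -4.53 and 4.54, and the highest hexamer, CGGAGA, stood at 4.88. It was also lowest in coding sequences (-5.74) but not in 5′ UTRs (-0.01, rank 2196), and the heptamers TCTCACA and CTCACAA were lowest of 16096 (-12.6 and -10.7). Next came CTCACAT (-8.33) and ACTCACA (-8.32), and genes with only these counted as holding the hexamer alone. Of 329 genes at least 2-fold lower with a 3′ UTR searched, 136 (41.3%) held a 7- or 8-base match, against 15.8% of 8837 others. Of lower genes named, ADAM19 holds 5 copies of the hexamer, SPARC and MYD88 3 each and CCND1 and RRM2 2 each. CXCL8 holds 1 with no 7- or 8-base match, and CSF2, VIM and PLAU hold none. Named genes on the higher side hold it too, with 3 copies in SOD2, 2 in RABIF and 1, within a 7-base match, in DNAJC3. Copies were not adjusted for UTR length, so these examples do not show that more copies go with lower values.

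Base composition of 3′ UTRs is argued against as the origin of the hexamer shift, since the lowest of 57 hexamers made of the same bases and sharing no 5-base stretch stood at -2.24. Distortion in genes with few exons is argued against by a standardised shift of -11.8 among genes with 5 or more exons. Pairing with the seed of a small RNA, the 5′ part of a microRNA or siRNA guide strand, is a candidate explanation. With words chosen on one random set of genes and measured on the 4583 others, CTCACA came first in both directions. Genes with a longer match differed from the rest with the hexamer by -0.18 ± 0.03 (805 against 771 genes) and -0.12 ± 0.04 (355 against 1213), with standard errors over genes. These contrasts are not alike. With words chosen on the second set, the longer match was CTCACAA alone, and genes with only TCTCACA counted with the rest. Genes with the hexamer followed by A differed from other genes with the hexamer by -0.16 ± 0.03 and -0.12 ± 0.04. The longer words differed between the sets (TCTCACA and CTCACAA), and of octamers over all genes CTCACAAA was lowest and TCTCACAA the fifth. The siRNA sequences were not analysed here, so whether the small RNA would be the targeting siRNA stays open. Loss of the target transcript itself cannot be told apart from it, because 1 group received a targeting siRNA and a second duplex would be needed.

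Matches of 7 or 8 bases in gene lists were counted after the hexamer had been seen, and no difference between lists was tested. Among lists below the central 95% of random lists in the main comparison, a position that NF-κB feedback and p53 targets lost under other settings, 3 of 22 NF-κB feedback targets, 5 of 23 invasion and mesenchymal genes, 5 of 37 mitotic genes, 7 of 43 DNA replication genes and 3 of 24 p53 targets held a match. Of their members at least 2-fold lower, 0 of 3, 2 of 9, 1 of 1, 3 of 4 and 0 of 2 did. NF-κB-induced cytokines, within the central 95% as a list, held a match in 0 of 9 genes, which include the 3 that were at least 2-fold lower. Without matched genes, each of the 5 lists was still below percentile 2.5. Few members were left out, so a list median could move little, and any effect of matched genes on other genes would remain. Whether the list differences are separate from the hexamer shift is therefore not decided by this.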
